A study of Homo sapiens with 16 samples.

How the data were processed

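Total RNA from LNCaP-1F5 cells was measured on 16 Illumina one-colour bead arrays with 48803 probes. The labels put the arrays in 6 groups: vehicle, DHT, Dex and DHT+Dex with 3 arrays each on slide 1, and CPA and RU486 with 2 arrays each on slide 2. All arrays entered the analysis, and each group was taken from the sample labels. No controls or other columns lay outside these 16 arrays.

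The deposited non-normalized table holds, per the file headers, the mean bead intensity of each probe on a linear scale, with neither background correction nor normalization, as the authors exported it from BeadStudio (version not given). Beside each intensity the deposited table holds a detection p-value, and what it was computed against is not stated. Numbers in this table use decimal commas, and 363 detection p-values written as 100 were read as 1. The deposited series matrix holds intensities that the authors had background-subtracted and quantile-normalized, as the values show: they include negative values, and every column has the median 8. Each of its columns ranked the probes exactly as its own array in the non-normalized table did (Spearman 1), while the best match to another array was at most 0.768. The non-normalized table was used for the main results and the series matrix as an alternative.

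Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, that is normexp background correction, an offset of 16, quantile normalization over the 16 arrays and log2. The table has no negative control probes, so neqc took the background from the detection p-values. Probes with a detection p under 0.01 on at least 2 arrays were kept (14492 probes). Of all probes, 28098 carried 1 gene symbol in the reference table, 13 carried several and 20692 had no listed gene. The 12473 kept probes with 1 symbol gave 9731 genes, each represented by its probe with the highest mean over the 16 arrays, and 2270 genes had several kept probes. Symbols were brought up to date, so METTL7A appears as TMT1A. Genes are identified by symbol, and the probe annotation gives no genome positions of the probes.

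The median raw signal ranged from 108 to 157 between arrays, and within each group the mean correlation between arrays was at least 0.981. The first 3 principal components held 56.2, 12.8 and 6.65% of the variance. Precision is limited by the number of arrays, and an undetected gene has no measured level. For such a gene, and for one detected on 1 array of a group only, a bound was computed from the lowest signal among detected probes on the same array.

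A linear model with 1 mean per group was fitted to the 16 arrays with limma (lmFit and eBayes at default settings, 10 residual and 4.54 prior degrees of freedom). The comparisons were DHT, Dex, DHT+Dex, CPA and RU486 against vehicle, DHT against Dex, DHT+Dex against DHT and against Dex, CPA against RU486, and the interaction of DHT and Dex. The tests were two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Confidence intervals are 95%. Gene lists (20, of which 17 had the required 3 tested members) were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and members were also counted adjusted over the list alone. The lists were androgen-induced, androgen-repressed and glucocorticoid-induced genes, metallothioneins, lipid synthesis, polyamine metabolism, G1/S, G2/M, the secretory pathway with the unfolded protein response, glycolysis, NF-kappaB, interferon-stimulated, heat shock and immediate-early genes, steroid receptors with cofactors, and neuroendocrine, luminal, basal, fibroblast and leukocyte markers. FKBP5 belongs to both hormone lists.

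Overlaps between comparisons that share the vehicle arrays were set against 100 simulations of unchanged groups that share simulated vehicle arrays. They were also set against the product of both shares (independent lists). The simulated noise was independent between genes. The comparisons, gene lists and the rule for named genes were fixed before the data were examined, as were the tests and alternatives, apart from those named elsewhere as chosen only after the result was seen. The rule took the 10 largest rises and falls with DHT, Dex and DHT+Dex against vehicle, 8 each way for DHT against Dex, CPA, RU486 and CPA against RU486, and 5 each way for the remaining comparisons. These had to pass the threshold, and except for the interaction every treated array had to lie beyond every comparison array. The rule added the 4 members of each list with the smallest p, and in comparisons with vehicle a fixed set that included KLK3, TMPRSS2, FKBP5, TSC22D3, PER1, SGK1, NR3C1 and FOXA1. Unnamed loci were passed over, and for lists that did not pass, members are named sparingly.

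The pipeline was tested on simulated data in which 200 of 9731 genes were changed by 1.5, 2 or 4-fold. In a design like DHT against vehicle 22.4, 82.1 and 100% of these were recovered, with 4.90% false calls. In a design like CPA against RU486 14.9, 65.7 and 95.5% were recovered, and for the interaction 0, 31.3 and 95.5%. A simulated list of 20 genes shifted by 0.5 gave a camera p of 9.43e-22, and 2 of 100 unshifted lists had a p under 0.05.

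The alternatives were no background correction, normexp with each array centred on its median and no quantile step (called median centring), neqc run on each slide alone, the authors' processed intensities, no detection filter, a filter on all arrays of a group, all probes tested separately, the mean of a gene's probes, eBayes with trend and robust options, array weights, the replicate number as a block, a fit on only the groups compared, an adjusted p under 0.01, a change of at least 1.5-fold, and leaving out each array in turn. For gene lists an estimated correlation, fry and the replicate block were tried. Splits of the arrays into other groups were counted where each group had at least 3 arrays. Probes with no listed gene were tested only to count how many changed.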

Results

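RNA levels were measured on 16 one-colour bead arrays of LNCaP-1F5 cells, a derivative of the androgen-sensitive LNCaP prostate cancer line that stably expresses the glucocorticoid receptor. After 3 days in charcoal-stripped medium the cells were exposed for 24 h to vehicle (3 arrays), 100 nM of the androgen 5α-dihydrotestosterone (DHT, 3 arrays), 100 nM of the glucocorticoid dexamethasone (Dex, 3 arrays) or both hormones (DHT+Dex, 3 arrays), all on slide 1. Slide 2 held 2 arrays with 1000 nM cyproterone acetate (CPA), a steroidal antiandrogen, and 2 arrays with mifepristone (RU486), a steroidal antagonist of the progesterone and glucocorticoid receptors. The labels give the RU486 dose as 100 nM in the design text and as 1000 nM in the treatment protocol. The design asks what an androgen and a glucocorticoid change in the same cells, alone and together, and what ligands known as antagonists change.

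Between 11425 probes (DHT+Dex replicate 3) and 13134 probes (DHT replicate 1) passed a detection p under 0.01, or 23.4 to 26.9% of the probes on an array. Group means were 12661 ± 149 probes with vehicle, 12697 ± 383 with DHT, 12422 ± 350 with Dex and 11818 ± 344 with DHT+Dex (SD, n = 3). They were 11982 ± 74.2 with CPA and 12728 ± 534 with RU486 (SD, n = 2). Of the probes, 9731 genes were tested. Values after a log2 change are its standard error (SE) from limma unless named otherwise, and a gene undetected in 1 group, or detected there on 1 array only, has a bound, written as "at least". The bound sets the brighter group's mean against, on each dim array, the higher of the lowest signal among detected probes and the dim probe's own signal. Of the genes given with a log2 change below, KLK3, SOCS2, TUBA3E, CD68, DBR1, SLC2A3 and TMT1A were detected on 2 of the 3 vehicle arrays. SYTL2 and PNLIP were detected on 2 of 3 arrays with DHT, ARG2, H19, SLC2A12 and ST6GALNAC1 with Dex, and AADAT, BCHE, GASK1B, MAK, PRAG1 and SERPINI1 with DHT+Dex. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

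**Figure D1:**
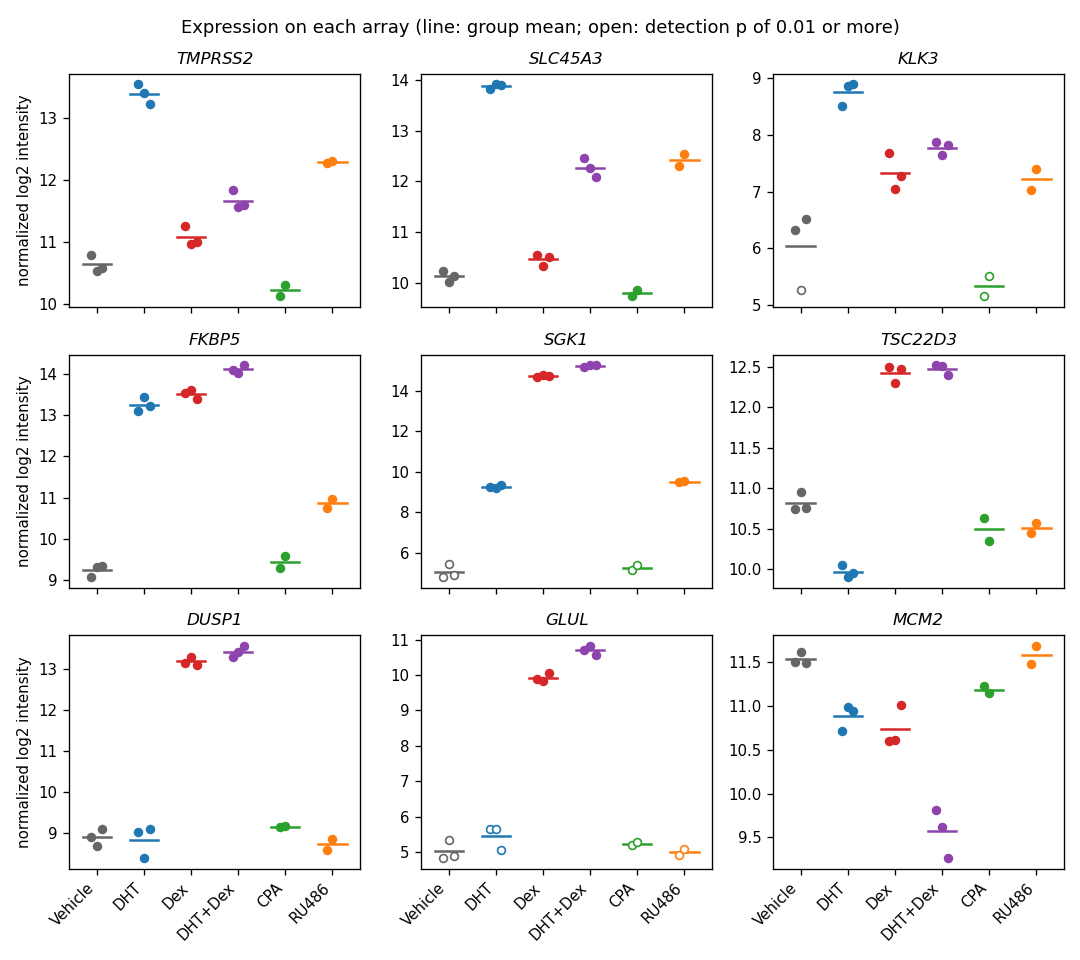
Normalized log2 intensity of 9 genes on each of the 16 arrays, by group, where a line marks the group mean and open points have a detection p of 0.01 or more. SLC45A3 and TMPRSS2 sit highest with DHT, while SGK1, DUSP1 and GLUL sit highest with Dex and DHT+Dex.

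DHT raised the classical androgen targets of prostate cells. KLK3, which encodes prostate-specific antigen, rose 6.54-fold (log2 2.71, SE 0.26, adjusted p = 3.48e-06). TMPRSS2, a membrane serine protease, rose 6.72-fold (2.75, SE 0.14) and SLC45A3, which encodes the membrane protein prostein, rose 13.3-fold (3.74, SE 0.13). FKBP5, an HSP90 co-chaperone of steroid receptors, rose 16-fold (log2 4.0, SE 0.14, adjusted p = 3.61e-11). The repressor of epithelial genes SNAI2 was at least 14.3-fold higher, MYBPC1 at least 14.2-fold, the sialyltransferase gene ST6GALNAC1 at least 12.2-fold. The kinase gene SGK1 was at least 8.75-fold higher, the growth factor antagonist gene NBL1 at least 6.65-fold and the phosphoinositide phosphatase gene INPP4B at least 6.04-fold. The protease gene PGC was at least 23.1-fold higher and the cytokine signalling inhibitor SOCS2 rose by 4.48 (SE 0.14). Among the largest falls were ACP3, which encodes prostatic acid phosphatase (-2.84, SE 0.13), the chemokine receptor gene ACKR3 (-2.91, SE 0.12) and the vesicle protein gene SYTL2 (-3.45, SE 0.20). The kinase inhibitor gene CAMK2N1 was at least 7.85-fold (adjusted p = 5.41e-06) and LRRC31 at least 8.02-fold lower. LRRN1 (-3.09, SE 0.14), GASK1B (-2.74, SE 0.18), CBLN2 (-2.61, SE 0.15) and SERPINI1 (-2.61, SE 0.20, with its other probe at -0.92) also fell, and PCED1B was at least 2.94-fold lower.

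Of 25 measured androgen-induced genes, 24 rose and 0 fell with DHT (24 adjusted over the list alone; camera adjusted p = 4.08e-42). Among them were the elongation factor gene ELL2 (3.52, SE 0.17) and the stress-response gene NDRG1 (3.40, SE 0.14). Of 9 androgen-repressed genes, 6 fell (7 adjusted over the list alone; adjusted p = 4.56e-07). DDC, an enzyme of amine synthesis, stood at -2.37 (SE 0.13) and UGT2B17, an androgen-glucuronidating enzyme, at -1.81 (SE 0.16). UGT2B11, a relative of UGT2B17, rose by 2.03 (SE 0.15). Among 22 glucocorticoid-induced genes 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 8.06e-08). Rises belonged to the receptor-feedback inhibitor ERRFI1 (2.37, SE 0.12) and the transcription factor ZBTB16 (2.23, SE 0.12). TSC22D3, which encodes the glucocorticoid-induced leucine zipper, moved the other way at -0.85 (SE 0.12, adjusted p = 0.000131), a call that ended with median centring (adjusted p = 0.202). All 3 measured metallothioneins, the metal-binding proteins, fell (3 adjusted over the list alone; adjusted p = 9.74e-07): MT2A at -2.38 (SE 0.18), MT1X at -2.07 (SE 0.12) and MT1F at -1.39 (SE 0.17).

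The lists of lipid synthesis and polyamine metabolism genes passed with DHT. Secretory pathway genes were shifted up but just missed the threshold (camera adjusted p = 0.0502). That list passed without Vehicle 1, Vehicle 3 or DHT 2 (adjusted p = 0.0434, 0.0240 and 0.0267), but not without Vehicle 2, DHT 1 or DHT 3. Of 18 cholesterol and fatty acid synthesis genes, 8 rose and 0 fell (9 adjusted over the list alone; adjusted p = 1.81e-06). They were led by the fatty acid elongase ELOVL5 (2.03, SE 0.15), HMGCS1 (1.03, SE 0.13), SC5D (0.77, SE 0.15) and INSIG1 (0.69, SE 0.14). Of 9 polyamine genes, 5 rose (6 adjusted over the list alone; adjusted p = 5.73e-06), with SAT1, an acetyltransferase of polyamine breakdown, at 3.21 (SE 0.13), ornithine decarboxylase ODC1 at 1.49 (SE 0.12) and spermine synthase SMS at 1.42 (SE 0.12). Of 7 luminal epithelial markers, KRT8 (1.45, SE 0.12), KRT18 (0.91, SE 0.26) and KRT19 (at least 2.20-fold) rose and CDH1 fell (-0.43, SE 0.12; 3 and 1 adjusted over the list alone). The list passed at adjusted p = 0.0426, but had adjusted p = 0.0800 with an estimated correlation, 0.0663 without Vehicle replicate 2 and 0.0674 without DHT replicate 3. KRT18 missed the threshold without Vehicle 1, Vehicle 2, DHT 2 or DHT 3 (adjusted p = 0.0653, 0.130, 0.0658 and 0.0944). CDH1 missed it without Vehicle 1, DHT 1 or DHT 3 (adjusted p = 0.0845, 0.0767 and 0.0518) and with median centring (adjusted p = 0.726). Of 20 G1/S and DNA replication genes, 6 fell (10 adjusted over the list alone; adjusted p = 8.63e-06). Among them were the replicative helicase gene MCM6 at -0.68 (SE 0.11) and thymidine kinase TK1 at -0.82 (SE 0.12), although 0 of the 20 passed with median centring. Of 20 G2/M genes only TOP2A fell (-0.57, SE 0.16, a call that ended without Vehicle 2, Vehicle 3, DHT 1 or DHT 3, with no filter, with array weights and with median centring; 0 adjusted over the list alone; adjusted p = 0.215), and the list median of -0.13 turned to 0.10 with median centring. FOXA1, the pioneer factor of the series title, stood at 0.01 (SE 0.11, adjusted p = 0.958). The probes of NR3C1, the glucocorticoid receptor gene, and PER1 were detected on 0 arrays, so these genes are not analysed here.

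Against vehicle, 1260 of 9731 genes passed an adjusted p of 0.05 with DHT (limma, Benjamini-Hochberg, n = 3 and 3), 619 up and 641 down, with 277 up and 207 down at least 2-fold. With each array centred on its median in place of quantile normalization, 722 passed (517 up, 205 down), and the median of all genes shifted by 0.21. Of the 326 called genes with several probes, 27 had probes of opposite sign.

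More genes passed with Dex than with DHT, and the largest rises included known glucocorticoid targets. SGK1 was at least 389-fold higher (adjusted p = 2.46e-15), the matrix protein gene CCN2 at least 113-fold, the small GTPase gene RASD1 at least 47.5-fold, SNAI2 at least 47.1-fold. The lipase gene PNLIP was at least 42.7-fold and PHACTR3 at least 27.1-fold higher. PGC was at least 197-fold higher, and the calcium-binding protein gene S100P rose by 6.55 (SE 0.24) and the near-identical tubulin genes TUBA3E and TUBA3D by 6.73 (SE 0.17) and 6.52 (SE 0.25). Falls were smaller: ACP3 at -1.98 (SE 0.13), GASK1B at -1.92 (SE 0.18), the androgen-glucuronidating enzyme UGT2B15 at -1.67 (SE 0.20) and the RNA sensor IFIH1 at -1.67 (SE 0.22). The arginine methyltransferase CARM1 stood at -1.67 (SE 0.20), the transcription factor MECOM at -1.62 (SE 0.18) and the arginase ARG2 at -1.60 (SE 0.28, adjusted p = 0.000621). INF2 fell by 1.74 (SE 0.26), with its other probes reaching -0.17, while SORBS3 was at least 2.37-fold and the transcription factor MYB at least 2.02-fold lower. KLK3 rose 2.45-fold (1.29, SE 0.26, adjusted p = 0.00228) and FKBP5 19.1-fold (4.26, SE 0.14). FOXA1 fell by 0.66 (SE 0.11, adjusted p = 0.000621) and TMPRSS2 rose by 0.44 (SE 0.14, adjusted p = 0.0272), but with median centring neither passed (adjusted p = 0.151 and 0.245). The TMPRSS2 call also ended without Vehicle 2, Vehicle 3 or Dex 1 (adjusted p = 0.0869, 0.0750 and 0.112).

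Of 22 glucocorticoid-induced genes, 19 rose and 0 fell with Dex (19 adjusted over the list alone; adjusted p = 1.96e-27). TIPARP, a target of ligand-activated receptors, rose by 5.71 (SE 0.14), ERRFI1 by 3.97 (SE 0.12) and TSC22D3 by 1.61 (SE 0.12), and CRISPLD2 was at least 15.9-fold higher. Of the 25 androgen-induced genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 6.29e-08). ELL2 stood at 4.16 (SE 0.17), NDRG1 at 1.65 (SE 0.14) and the prostaglandin-degrading enzyme HPGD at least 4.45-fold higher. All 9 androgen-repressed genes fell (9 adjusted over the list alone; adjusted p = 7.23e-06), including ACKR3 (-1.19, SE 0.12) and DDC (-0.94, SE 0.13). MT1F (-0.89, SE 0.17), MT2A (-0.81, SE 0.18) and MT1X (-0.44, SE 0.12) fell (3 adjusted over the list alone; list adjusted p = 0.0269). The list had adjusted p = 0.0979 with an estimated correlation, 0.0501 without Vehicle 2 and 0.0593 with median centring, which also ended these 3 calls. MT1X missed the threshold without Vehicle 2 or Dex 2 as well (adjusted p = 0.0615 and 0.0674).

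Of the 18 lipid synthesis genes, 11 rose and 1 fell with Dex (11 and 1 adjusted over the list alone; adjusted p = 2.58e-05). ELOVL5 stood at 2.00 (SE 0.15), the desaturase FADS1 at 1.87 (SE 0.13) and INSIG1 at 1.14 (SE 0.14). Secretory pathway genes rose too, 10 up and 2 down of 20 (10 and 2 adjusted over the list alone; adjusted p = 0.000810). The transcription factor CREB3L2 stood at 1.70 (SE 0.13) and the chaperone DNAJB9 at 1.23 (SE 0.13). Of 20 G1/S genes, 15 fell (18 adjusted over the list alone; adjusted p = 4.13e-07), among them the replication licensing factor CDT1 (-1.52, SE 0.25) and MCM10 (-0.99, SE 0.18). Of 20 G2/M genes, 7 fell (8 adjusted over the list alone; adjusted p = 0.000282), with the mitotic kinesin KIF20A at -0.86 (SE 0.14). Median centring left 2 and 1 falls in these lists, with medians of -0.49 and -0.36. The polyamine list did not pass (2 up and 1 down of 9, 4 and 2 adjusted over the list alone; adjusted p = 0.152), although SAT1 rose by 1.54 (SE 0.13) and ODC1 by 1.49 (SE 0.12). In all, 2611 genes passed (limma, n = 3 and 3), 1232 up and 1379 down, with 499 up and 161 down at least 2-fold. Of these, 71 of the 655 called genes with several probes had probes of opposite sign. With median centring 1031 genes passed (758 up, 273 down).

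The 2 hormones changed many of the same genes in the same direction. In the same cells, 661 genes passed with both and with the same sign, 316 up (78.4 for independent lists) and 345 down (90.8 for independent lists). Unchanged groups with simulated shared vehicle arrays shared at most 1. Their noise was independent between genes, so almost no calls arise there, and this number is no measure for the 661. The shared vehicle arrays can raise the overlap. Another 75 genes passed with opposite signs, 30 of them up with DHT and down with Dex. Across 9731 genes, which are not independent replicates, the log2 changes had r = 0.470. Unchanged groups that share the vehicle arrays gave a mean r of 0.50, so r does not separate the responses from shared arrays, whereas the covariance was 0.169 against 0.0206 in these simulations. With median centring, 283 genes were shared with the same sign.

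**Figure D2:**
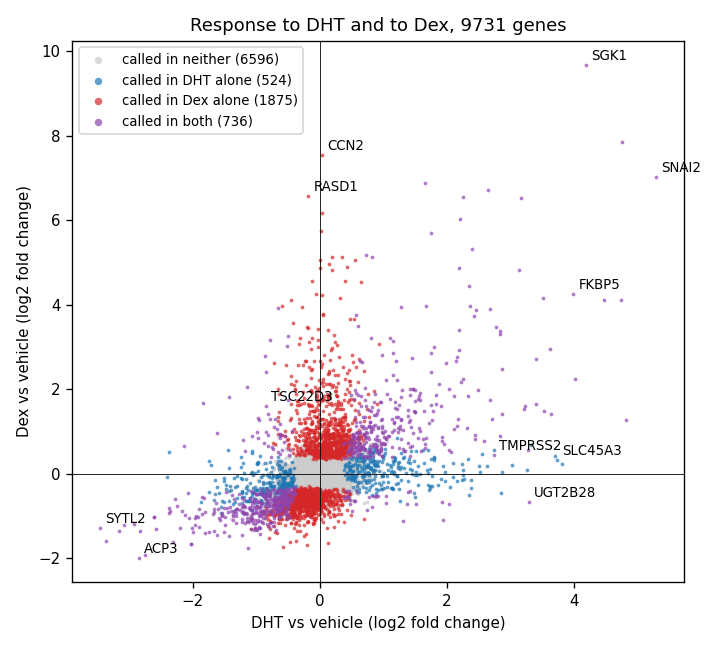
Log2 change with Dex against log2 change with DHT, each relative to vehicle, for 9731 genes coloured by where they passed adjusted p of 0.05. SNAI2 and FKBP5 rose with both hormones, CCN2 and RASD1 with Dex, and SLC45A3 and TMPRSS2 lie farther along the DHT axis.

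Compared directly, DHT exceeded Dex at androgen-induced genes and Dex exceeded DHT at glucocorticoid-induced genes. UGT2B28, of a family of near-identical glucuronidating enzymes, was higher with DHT by 3.97 (SE 0.15), ST6GALNAC1 by 3.55 (SE 0.14), and SLC45A3 by 3.41 (SE 0.13). PRAG1 was at least 7.59-fold higher (adjusted p = 2.64e-05), and TMEFF2, a membrane proteoglycan of prostate, was higher by 3.18 (SE 0.14) and the glucose transporter SLC2A12 by 3.05 (SE 0.37). PCDH20 was at least 7.37-fold and INPP4B at least 5.72-fold higher with DHT. With Dex, CCN2 was at least 114-fold, RASD1 at least 47.6-fold, PHACTR3 at least 27.2-fold, the cystatin gene CST1 at least 24.9-fold and SCNN1G, a subunit of the epithelial sodium channel, at least 13.6-fold higher. DHT minus Dex was -5.47 (SE 0.15) for SGK1, -5.22 (SE 0.16) for PNLIP and -5.05 (SE 0.13) for TLCD4. Androgen-induced genes were higher with DHT at 19 and lower at 2 of 25 (20 and 2 adjusted over the list alone; adjusted p = 4.76e-14). Examples were TMPRSS2 (2.31, SE 0.14) and the kinase gene MAK (at least 3.91-fold). Glucocorticoid-induced genes were lower with DHT at 17 and higher at 0 of 22 (17 adjusted over the list alone; adjusted p = 1.23e-19). Examples were the phosphatase gene DUSP1 (-4.33, SE 0.18) and glutamine synthetase GLUL (at least 14-fold lower).

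Metallothioneins were also lower with DHT (0 higher and 3 lower of 3, 3 adjusted over the list alone; adjusted p = 0.00160), with MT1X at -1.63 (SE 0.12). G2/M genes were higher (5 higher and 0 lower of 20, 5 adjusted over the list alone; adjusted p = 0.00719), with KIF20A at 0.63 (SE 0.14). Other lists passed camera alone. Androgen-repressed genes (1 higher, 5 lower of 9, and the same adjusted over the list alone) had adjusted p = 0.0433 and polyamine genes (3 higher, 1 lower of 9) 0.0266. Secretory pathway genes (1 higher, 6 lower of 20) had 0.0357 and fibroblast markers (0 higher, 2 lower of 3) 0.0374. Each had adjusted p = 0.0950 with an estimated correlation, and median centring ended the first 3 (adjusted p = 0.0584, 0.0505 and 0.204). No background correction ended the calls of secretory pathway genes and fibroblast markers (adjusted p = 0.0564 and 0.0565). Androgen-repressed genes also missed the threshold without any vehicle array, DHT 2, DHT 3 or Dex 1, secretory pathway genes without DHT 2 or Dex 2, and fibroblast markers without DHT 1, DHT 2 or Dex 1 (adjusted p from 0.0515 to 0.0872). Lipid synthesis (3 higher, 4 lower of 18; adjusted p = 0.581) and G1/S genes (2 higher, 1 lower of 20; adjusted p = 0.0629) did not pass. G1/S genes passed, higher with DHT, without DHT 1, Dex 3 or DHT+Dex 3 (adjusted p = 0.0273, 0.0410 and 0.0498). Between DHT and Dex 2051 genes differed (limma, n = 3 and 3), 968 higher and 1083 lower with DHT, and 1094 with median centring.

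With DHT and Dex together the most genes passed, and most of the cell cycle genes fell. Of 20 G1/S and replication genes 19 fell (20 adjusted over the list alone; median -1.28; adjusted p = 2.65e-10). Among them were the helicase subunits MCM2 at -1.97 (SE 0.16), MCM6 at -1.54 (SE 0.11) and MCM3 at -1.41 (SE 0.12) and the methylation maintenance factor UHRF1 at -1.85 (SE 0.13). Of 20 G2/M genes 18 fell (18 adjusted over the list alone; median -0.94; adjusted p = 5.62e-07). KIF20A stood at -1.75 (SE 0.14), the mitotic kinase AURKB at -1.59 (SE 0.11) and TOP2A at -1.37 (SE 0.16). With median centring 19 and 11 of these lists fell. The largest rises included genes that also rose with Dex: SGK1 at least 545-fold, CCN2 at least 153-fold, RASD1 at least 92.1-fold, and PNLIP at least 67.2-fold. SNAI2 was at least 62.3-fold, TUBA3C at least 61.6-fold and PHACTR3 at least 43.3-fold higher, with PGC at least 359-fold, TUBA3E at 7.60 (SE 0.17) and TUBA3D at 7.42 (SE 0.25). The largest falls included genes that each hormone alone had lowered, such as ACP3, GASK1B and ACKR3. CBLN2 was at least 22.8-fold, LRRN1 at least 14.4-fold, SYTL2 at least 10.2-fold and MECOM at least 7.83-fold lower, while ACP3 fell 27.6-fold (-4.78, SE 0.13). ACKR3 (-4.05, SE 0.12), UGT2B15 (-3.88, SE 0.20), the cholinesterase gene BCHE (-3.78, SE 0.22), SERPINI1 (-3.56, SE 0.20, with its other probe at -0.79) and GASK1B (-3.56, SE 0.18) fell as well.

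**Figure D3:**
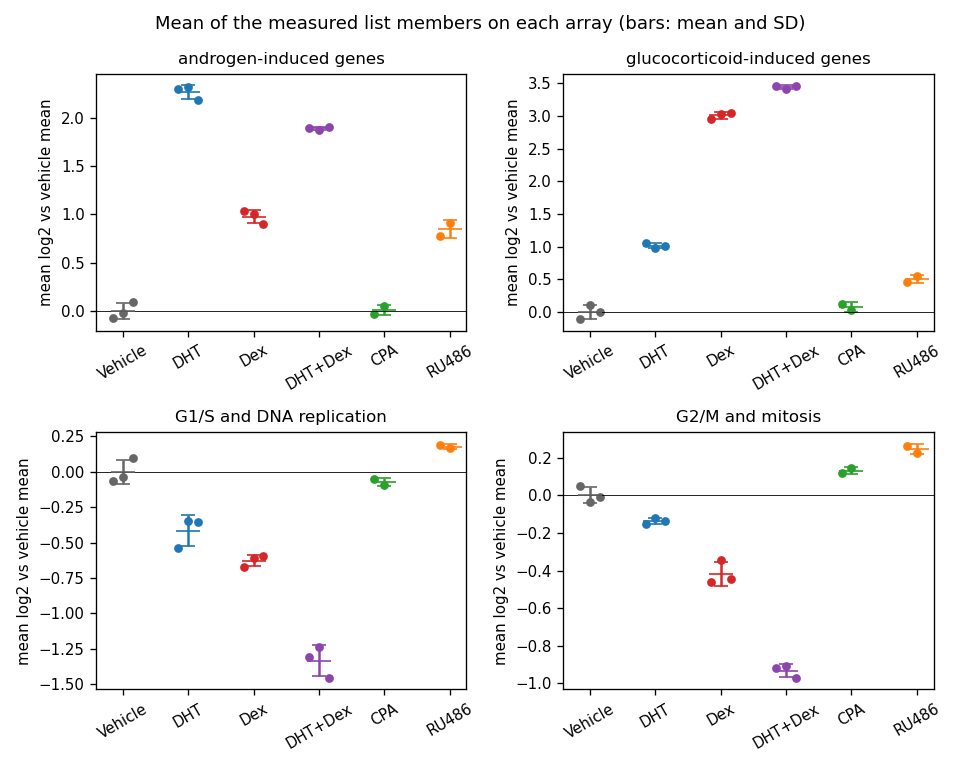
Mean log2 change from the vehicle mean over the measured members of 4 gene lists, 1 point per array, with bars at the group mean and SD. For G1/S genes the DHT+Dex arrays lie at -1.34 ± 0.11, below DHT (-0.41 ± 0.11) and Dex (-0.63 ± 0.04).

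With both hormones 22 of 25 androgen-induced genes rose (22 adjusted over the list alone; adjusted p = 1.91e-14), with FKBP5 at 4.86 (SE 0.14), KLK3 at 1.73 (SE 0.26) and TMPRSS2 at 1.03 (SE 0.14). The hormones together lowered 8 of 9 androgen-repressed genes (8 adjusted over the list alone, where 1 also rose; adjusted p = 9.76e-06), with DDC at -3.31 (SE 0.13). Of 22 glucocorticoid-induced genes 20 rose (20 adjusted over the list alone; adjusted p = 7.88e-20), with TIPARP at 6.70 (SE 0.14), ERRFI1 at 4.87 (SE 0.12) and TSC22D3 at 1.65 (SE 0.12). The 3 metallothioneins fell (3 adjusted over the list alone; adjusted p = 0.000539), MT2A at -2.66 (SE 0.18). Lipid synthesis genes rose at 11 and fell at 2 of 18 (12 and 2 adjusted over the list alone; adjusted p = 0.000130), with FADS1 at 2.44 (SE 0.13) and HMGCS1 at 1.49 (SE 0.13). Secretory pathway genes rose at 11 and fell at 2 of 20 (11 and 2 adjusted over the list alone; adjusted p = 0.000709), with DNAJB9 at 2.31 (SE 0.13). Polyamine genes rose at 4 and fell at 1 of 9 (4 and 1 adjusted over the list alone; adjusted p = 0.0398), but had adjusted p = 0.124 with an estimated correlation, 0.0749 with median centring and 0.0545, 0.0728 and 0.0717 without Vehicle 1, Vehicle 2 and DHT+Dex 1. FOXA1 fell by 0.76 (SE 0.11, adjusted p = 6.45e-05). In total 4614 genes passed (limma, n = 3 and 3), 2000 up and 2614 down, with 855 up and 837 down at least 2-fold. The highest adjusted p among the 20 genes with the largest changes was 3.31e-09. Median centring gave 2866 genes (1657 up, 1209 down) and shifted the median of all genes by 0.16. Of the called genes, 119 of 1162 with several probes had probes of opposite sign.

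Adding Dex to DHT raised glucocorticoid targets and lowered cell cycle genes and a part of the androgen response. CCN2 was at least 153-fold, RASD1 at least 92.5-fold, PHACTR3 at least 43.4-fold and SCNN1G at least 33.0-fold higher than with DHT alone, and SGK1 was higher by 5.96 (SE 0.15). TMEFF2 (-2.38, SE 0.14), AADAT, an enzyme of tryptophan breakdown (-2.38, SE 0.27, with its other probe at -1.19), PRAG1 (-2.49, SE 0.41, adjusted p = 0.000256) and TM4SF1 (-2.34, SE 0.15) were lower, and CBLN2 was at least 3.74-fold lower. Androgen-induced genes were higher at 6 and lower at 14 of 25 (6 and 16 adjusted over the list alone), with TMPRSS2 at -1.72 (SE 0.14), SLC45A3 at -1.60 (SE 0.13) and MAK at -1.74 (SE 0.17) but the cytokine receptor LIFR at 2.83 (SE 0.24). The list passed camera (adjusted p = 0.0265) but had adjusted p = 0.199 with an estimated correlation. Glucocorticoid-induced genes were higher at 20 of 22 (20 adjusted over the list alone; adjusted p = 9.03e-21), and androgen-repressed genes were lower still at 7 of 9 (7 adjusted over the list alone; adjusted p = 0.000335), with BCHE at -1.93 (SE 0.22). G1/S genes were lower at 18 (19 adjusted over the list alone; adjusted p = 6.25e-09), as were G2/M genes at 17 of 20 (18 adjusted over the list alone; adjusted p = 1.01e-07). Secretory pathway genes were higher at 9 and lower at 1 of 20 (12 and 2 adjusted over the list alone; adjusted p = 0.00422). Metallothioneins (1 lower of 3; adjusted p = 0.155), lipid synthesis (10 higher, 3 lower of 18; adjusted p = 0.0712) and polyamine genes (1 higher, 3 lower of 9; adjusted p = 0.308) did not pass. In this comparison 3495 genes differed (limma, n = 3 and 3), 1534 higher and 1961 lower, and 2017 with median centring.

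Adding DHT to Dex raised androgen targets further and lowered cell cycle genes and metallothioneins. TEDDM1 was at least 7.50-fold, CTNNA2, an adhesion gene (adjusted p = 5.83e-06), at least 2.46-fold and ORM2, a plasma glycoprotein gene, at least 2.11-fold higher than with Dex alone. The imprinted noncoding RNA H19 (3.16, SE 0.18) and ST6GALNAC1 (2.51, SE 0.14) were higher too. CBLN2 was at least 11.2-fold and COLCA1 at least 6.20-fold lower, and ACKR3 (-2.85, SE 0.12), BCHE (-2.83, SE 0.22) and ACP3 (-2.80, SE 0.13) were lower. Androgen-induced genes were higher at 17 and lower at 0 of 25 (20 adjusted over the list alone; adjusted p = 1.15e-18), with SLC45A3 at 1.81 (SE 0.13) and STEAP4 at least 2.13-fold. Androgen-repressed genes were lower at 6 and higher at 1 of 9 (6 and 1 adjusted over the list alone; adjusted p = 2.75e-07). Glucocorticoid-induced genes were higher at 8 of 22 (8 adjusted over the list alone; adjusted p = 3.00e-07), among them ERRFI1 (0.89, SE 0.12) and TIPARP (0.99, SE 0.14), whose calls ended with median centring (adjusted p = 0.0747 and 0.0597). The 3 metallothioneins were lower (3 adjusted over the list alone; adjusted p = 2.75e-07), MT1X at -1.92 (SE 0.12). G1/S genes were lower at 13 (16 adjusted over the list alone; adjusted p = 8.53e-13) and G2/M genes at 10 of 20 (12 adjusted over the list alone; adjusted p = 2.42e-08), with MCM2 at -1.18 (SE 0.16). Median centring left 3 and 0 of them. Lipid synthesis (4 higher of 18; adjusted p = 0.0385), polyamine (2 higher of 9; adjusted p = 0.0448) and secretory pathway genes (2 higher of 20; adjusted p = 0.0385) passed camera. With an estimated correlation they had adjusted p = 0.110, adjusted p = 0.123 and adjusted p = 0.116, and with median centring 0.0583, 0.124 and 0.0583. With the replicate number as a block polyamine genes had adjusted p = 0.0529. Each was also lost without Dex 1 (adjusted p = 0.119, 0.110 and 0.0752). Lipid synthesis failed without DHT+Dex 1, polyamine genes without Vehicle 1, Vehicle 2, DHT 3, Dex 3 or DHT+Dex 1, and secretory pathway genes without Dex 3 or DHT+Dex 3 (adjusted p from 0.0520 to 0.118). Here 1233 genes differed (limma, n = 3 and 3), 482 higher and 751 lower, against 383 with median centring and 785 without Dex replicate 3.

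The interaction term, the DHT effect with Dex minus the DHT effect without it, was mostly negative at genes that both hormones raised. It was -3.39 (SE 0.19) for FKBP5, -3.46 (SE 0.20) for SOCS2, -3.89 (SE 0.28) for PGC, -4.90 (SE 0.20) for SNAI2 and -3.71 (SE 0.21) for SGK1. SNAI2 and SGK1 were undetected with vehicle and PGC was detected on 1 of 3 vehicle arrays, so these terms rest in part on background, and on the DHT+Dex arrays SGK1 and PGC lay within 1 log2 unit of the brightest probe. Positive terms belonged to TEDDM1 (3.44, SE 0.21) and H19 (3.28, SE 0.25), both undetected with vehicle and with DHT, and TEDDM1 also with Dex. They also belonged to the sphingosine phosphate receptor S1PR3 (2.28, SE 0.22), CAMK2N1 (2.14, SE 0.48, adjusted p = 0.0263) and the growth factor-binding protein IGFBP3 (2.09, SE 0.26). With DHT, S1PR3 was undetected and CAMK2N1 and IGFBP3 were detected on 1 of 3 arrays, so the positive terms rest in part on background too. Of 25 androgen-induced genes 17 had a negative and 0 a positive term (19 and 1 adjusted over the list alone; adjusted p = 6.98e-26), including ELL2 (-3.00, SE 0.23), TMPRSS2 (-2.16, SE 0.19) and SLC45A3 (-1.93, SE 0.18). Of 22 glucocorticoid-induced genes 9 were negative and 2 positive (9 and 3 adjusted over the list alone; adjusted p = 0.00202), with CRISPLD2, undetected with vehicle, at -2.16 (SE 0.20), but their median of -0.02 turned to 0.03 with no background correction. Negative terms also marked polyamine (2 of 9, 4 adjusted over the list alone; adjusted p = 7.41e-05), G2/M (3 of 20, 5 adjusted over the list alone; adjusted p = 2.32e-05), as well as lipid synthesis genes (1 of 18, 1 adjusted over the list alone; adjusted p = 0.00415). SAT1 stood at -1.86 (SE 0.18), TPX2 at -0.77 (SE 0.17) and ELOVL5 at -1.52 (SE 0.22). G1/S genes (1 of 20, 1 adjusted over the list alone) had adjusted p = 0.00295, but adjusted p = 0.173 with an estimated correlation. Androgen-repressed genes (1 positive, 1 negative of 9) had adjusted p = 0.846, with a mean of 0.06 and a median of -0.12, and metallothioneins (0 of 3) also had 0.846. The term passed at 292 genes (limma, n = 3 per group), 88 positive and 204 negative, and at 108 with median centring (21 positive, 87 negative), which shifted the median of all genes at -0.14 and ended the call of TPX2 (adjusted p = 0.430). TPX2 also missed the threshold without Vehicle 1, Dex 1 or Dex 3 (adjusted p from 0.0516 to 0.0592). CAMK2N1 missed it without Vehicle 1, Vehicle 3, DHT 1, DHT 2, Dex 2, Dex 3 or DHT+Dex 3 (adjusted p from 0.0538 to 0.0689). The G2/M call of AURKB (adjusted p = 0.0355) ended without each slide 1 array but Dex 1 (0.0531 to 0.0863). That of CENPF (0.0320) held only without Vehicle 2, DHT 1, Dex 3 or DHT+Dex 2 (otherwise 0.0647 to 0.0779). The G1/S call of UHRF1 (0.0465) held only without Vehicle 3 or Dex 2 (otherwise 0.0679 to 0.113).

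With CPA the classical hormone targets did not pass the test. The change was -0.42 (SE 0.15, adjusted p = 0.162) for TMPRSS2, 0.20 (SE 0.15, adjusted p = 0.538) for FKBP5, -0.32 (SE 0.13, adjusted p = 0.223) for TSC22D3 and 0.00 (SE 0.13, adjusted p = 1.00) for FOXA1. KLK3 was undetected with CPA (adjusted p = 0.239), and SGK1 was undetected in both groups. Only UAP1 of 25 androgen-induced genes (1.09, SE 0.20), only TMT1A of 22 glucocorticoid-induced genes (1.59, SE 0.34) and 0 of 9 androgen-repressed genes passed (1, 1 and 1 adjusted over the list alone). Without CPA 1 or CPA 2 neither gene passed (adjusted p = 0.0935 and 0.143 for UAP1, 0.207 and 0.125 for TMT1A), and TMT1A also failed without Vehicle 1 or Vehicle 3 (0.0857 and 0.0538). UAP1 rose with RU486 as well (1.34). The lists had adjusted p of 0.888, 0.871 and 0.871, and the mean of 0.05 and median of -0.08 of the androgen-repressed genes differed in sign. The largest rises were those of the Wnt receptor FZD6 (2.09, SE 0.34, adjusted p = 0.00743) and the RNA debranching enzyme DBR1 (2.01, SE 0.27, with its other probe at 0.79). COPS2 was at least 3.06-fold, TXNL1 at least 3.04-fold, SNX10 at least 2.62-fold, ZFP36L1 at least 2.50-fold (adjusted p = 0.0215), PERP at least 2.43-fold and OSBPL8 at least 2.22-fold higher, the last with its other probe at -0.60. The largest falls were RNF6 (at least 1.73-fold, adjusted p = 0.0290), CRTC1 (at least 1.41-fold), CCNL2 (at least 1.82-fold, adjusted p = 0.0425), SCAMP2 (at least 1.92-fold), JOSD2 (-1.10, SE 0.23), GRK6 (-1.06, SE 0.17), SNAP23 (-1.01, SE 0.24, with its other probe at 0.96) and RNF185 (-1.0, SE 0.21). With median centring none of these 8 falls passed (adjusted p from 0.0604 for RNF6 to 0.332 for SNAP23). Without CPA 1 none of these 16 rises and falls passed (adjusted p from 0.0557 to 0.178), and without CPA 2 only TXNL1 and DBR1 did (others 0.0617 to 0.374). PERP, ZFP36L1, RNF6, CCNL2, JOSD2, SNAP23 and RNF185 also failed without at least 1 of the vehicle arrays (0.0503 to 0.132). All of these largest rises, and the falls of RNF6, SCAMP2 and SNAP23, passed with the same sign with RU486. FZD6 stood there at 1.83 and TXNL1 at 1.97, so these genes may follow the slide and not CPA. The other named falls did not pass with RU486.

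No list passed with CPA. Metallothioneins (0 of 3; adjusted p = 0.871), lipid synthesis (1 up of 18; adjusted p = 0.941), polyamine (0 of 9; adjusted p = 0.871), G1/S (1 down of 20; adjusted p = 0.755), G2/M (0 of 20; adjusted p = 0.755) and secretory pathway genes (0 of 20; adjusted p = 0.755) all stayed above 0.05. At an unadjusted p under 0.05 stood 1669 genes, and 238 passed after adjustment (limma, n = 2 and 3), 185 up and 53 down, with median centring giving 217 up and 1 down. Of these, 30 had the sign of their DHT call (24 up against 11.8 for independent lists, 6 down against 3.49) and 6 the opposite, and 39 had the sign of their Dex call (25 up against 23.4, 14 down against 7.51) and 22 the opposite. These comparisons share the vehicle arrays, which can raise the overlap. The covariance of the CPA change was 0.0265 with the DHT change and 0.0200 with the Dex change, against 0.0207 for each in simulated unchanged groups. Median CPA changes were 0.01 and -0.11 over genes that rose and fell with DHT, and -0.01 and -0.08 over genes that rose and fell with Dex. With median centring they were 0.22, 0.09, 0.18 and 0.17, so 3 of the 4 changed sign, and those of 0.01 and -0.01 also changed sign without single arrays. CPA and vehicle arrays lie on different slides, so slide and compound cannot be told apart in this comparison, and the count rested on single arrays: 1 gene passed without CPA replicate 1, 15 without CPA replicate 2, 128 without Vehicle replicate 1 and 150 without Vehicle replicate 2. The overlap with DHT was 0, 3, 11 and 19 genes without CPA replicate 1, CPA replicate 2, Vehicle replicate 1 and DHT replicate 1, and that with Dex 0, 4 and 24 without CPA replicate 1, CPA replicate 2 and Vehicle replicate 1.

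On the RU486 arrays androgen-induced genes were higher and androgen-repressed genes lower than with vehicle. SGK1 was at least 10.5-fold (adjusted p = 8.65e-10) and MYBPC1 at least 5.41-fold higher, the homeodomain gene HOPX at least 4.68-fold and PGC at least 3.72-fold. SLC45A3 rose 4.88-fold (2.29, SE 0.14), TMPRSS2 3.13-fold (1.64, SE 0.15), FKBP5 3.07-fold (1.62, SE 0.15) and KLK3 2.26-fold (1.18, SE 0.30, adjusted p = 0.0372). PMEPA1, an inhibitor of growth factor signalling (2.81, SE 0.21, with its other probes reaching 1.29), TMEFF2 (2.61, SE 0.16) and TUBA3D (2.32, SE 0.28) rose as well. SYTL2 (-1.95, SE 0.22), GALNT18 (-1.73, SE 0.23), ACP3 (-1.72, SE 0.14), UGT2B15 (-1.64, SE 0.23) and CAMK2N1 (-1.43, SE 0.38, adjusted p = 0.0495, and 0.0622 with median centring) fell, and PKNOX2 was at least 2.46-fold, the sterol transporter ABCG1 at least 2.38-fold and RNF6 at least 2.04-fold lower. KLK3 missed the threshold without Vehicle 2, RU486 1 or RU486 2 (adjusted p = 0.0735, 0.119 and 0.313), ABCG1 without RU486 2 (0.0661) and RNF6 without either RU486 array (0.0605 and 0.162). CAMK2N1 missed it without any 1 of the 5 arrays (0.0921 to 0.281). TSC22D3 stood at -0.31 (SE 0.13, adjusted p = 0.218) and FOXA1 at -0.12 (SE 0.13, adjusted p = 0.646).

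With RU486, 15 of 25 androgen-induced genes rose and 0 fell (15 and 1 adjusted over the list alone; adjusted p = 7.81e-16), and 6 of 9 androgen-repressed genes fell (6 adjusted over the list alone; adjusted p = 6.76e-05). Of the latter, DDC (-1.08, SE 0.14) and ACKR3 (-0.63, SE 0.14) lost their calls with median centring (adjusted p = 0.109 and 0.577), ACKR3 also without Vehicle 3, RU486 1 or RU486 2 (adjusted p = 0.0511, 0.187 and 0.109). Of 22 glucocorticoid-induced genes 5 rose (7 adjusted over the list alone; adjusted p = 0.000498), including ZBTB16 (1.12, SE 0.14) and the transcription factor CEBPD (1.09, SE 0.24). MT2A (-1.05, SE 0.20) and MT1X (-0.94, SE 0.14) fell among the 3 metallothioneins (2 adjusted over the list alone; adjusted p = 0.000498), but with median centring neither passed (adjusted p = 0.133 and 0.181). G2/M genes were shifted up (adjusted p = 0.00553), with CDK1 alone rising of 20 (3 adjusted over the list alone) and losing its call with median centring (adjusted p = 0.10). G1/S genes had adjusted p = 0.0260 (PCNA alone rose of 20, 1 adjusted over the list alone) and adjusted p = 0.301 with an estimated correlation and 0.117 with median centring. Without RU486 1 or RU486 2, CEBPD, MT2A, CDK1 and PCNA also missed the threshold (adjusted p from 0.0626 to 0.282), as CDK1 did without each vehicle array (0.0565 to 0.104). The G1/S list was lost without Vehicle 1, Vehicle 2 or RU486 1 (adjusted p = 0.0616, 0.0720 and 0.0739). Lipid synthesis (2 up of 18; adjusted p = 0.206), polyamine (1 up of 9; adjusted p = 0.114) and secretory pathway genes (0 of 20; adjusted p = 0.222) did not pass.

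Of the 424 genes that passed with RU486 (limma, n = 2 and 3; 288 up, 136 down), 195 had the sign of their DHT call (115 up against 18.3 for independent lists, 80 down against 8.96) and 5 the opposite. For Dex, 152 had the same sign (87 up against 36.5, 65 down against 19.3) and 38 the opposite. These comparisons share the vehicle arrays, which can raise the overlap. The covariance of the RU486 change was 0.0904 with the DHT change and 0.0637 with the Dex change, against 0.0206 and 0.0207 in simulated unchanged groups. Median RU486 changes were 0.24 and -0.30 over genes that rose and fell with DHT, and 0.04 and -0.11 over genes that rose and fell with Dex. With median centring they were 0.58, -0.25, 0.33 and 0.06, so the last changed sign. Slide and compound cannot be told apart here either, and median centring gave 379 up and 12 down. Single arrays moved the count, since 118 and 97 genes passed without RU486 replicate 1 and without RU486 replicate 2. Without these arrays the overlap with DHT was 76 and 62 genes and that with Dex 63 and 48.

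CPA and RU486, both steroids, differed within slide 2 mainly at androgen-responsive genes. The doses were 1000 nM for CPA and either 100 or 1000 nM for RU486, so the labels do not settle whether the doses matched. CPA minus RU486 was -2.65 (95% confidence interval -3.02 to -2.29) for TMEFF2, -2.62 (-2.95 to -2.29) for SLC45A3 and -2.58 (-3.08 to -2.09) for PMEPA1, whose other probes reached -1.05. SGK1 was at least 8.95-fold, MYBPC1 at least 4.62-fold, HOPX at least 4.08-fold, PGC at least 3.28-fold and ANKRD22 at least 1.69-fold lower with CPA. It was 1.88 (1.36 to 2.39) for SYTL2, 1.62 (1.29 to 1.96) for ACP3 and 1.47 (1.09 to 1.84) for LRRN1. GALNT18 (1.29, 0.75 to 1.84), PCED1B (1.17, 0.66 to 1.68), ABCG1 (at least 2.02-fold, adjusted p = 0.0284), PKNOX2 (at least 1.88-fold) and HOXC13 (1.11, 0.68 to 1.54) were also higher with CPA, but lost their calls with median centring (adjusted p from 0.114 for GALNT18 to 0.530 for HOXC13). These 5 genes and HOPX each missed the threshold without any 1 of 3 of the slide 2 arrays, CPA 2 always among them (adjusted p from 0.0518 to 0.416).

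Androgen-induced genes were lower with CPA at 12 and higher at 0 of 25 (14 adjusted over the list alone; adjusted p = 5.48e-22), with TMPRSS2 at -2.06 (SE 0.17) and the efflux transporter ABCC4 at -1.69 (SE 0.20). Androgen-repressed genes were higher at 2 of 9 (5 adjusted over the list alone; adjusted p = 5.91e-10), ACKR3 by 1.03 (SE 0.15) and DDC by 0.94 (SE 0.16), and neither passed with median centring (adjusted p = 0.607 and 0.778). Without CPA 2 or RU486 1 neither passed (adjusted p from 0.0518 to 0.139), and DDC also failed without RU486 2 (0.0994). Glucocorticoid-induced genes were lower at 4 of 22 (4 adjusted over the list alone; adjusted p = 5.28e-05), with FKBP5 at -1.42 (SE 0.17) and ZBTB16 at -1.33 (SE 0.15). Metallothioneins were higher (1 of 3, 2 adjusted over the list alone; adjusted p = 4.12e-05), MT1X by 0.88 (SE 0.15), a call that ended with median centring (adjusted p = 0.951) and without each slide 2 array (0.0608 to 0.138). G1/S genes were lower (1 of 20, 1 adjusted over the list alone; adjusted p = 2.58e-05), with adjusted p = 0.0532 with an estimated correlation. The called member, MCM5, lay close to the threshold (limma adjusted p = 0.0488). Without single slide 2 arrays its change ranged from -0.59 to -0.87. Lipid synthesis (1 lower of 18; adjusted p = 0.0621), polyamine (1 lower of 9; adjusted p = 0.288), G2/M (0 of 20; adjusted p = 0.0985) and secretory pathway genes (0 of 20; adjusted p = 0.462) did not pass. Lipid synthesis passed, lower with CPA, with no background correction (adjusted p = 0.0428) and without DHT+Dex 1 (adjusted p = 0.0489).

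Between CPA and RU486 97 genes differed (limma, n = 2 and 2), 28 higher and 69 lower with CPA, and 32 with median centring (4 higher, 28 lower). The count was 40 without CPA replicate 1, 21 without CPA replicate 2, 26 without RU486 replicate 1 and 25 without RU486 replicate 2. These arrays share none with the DHT comparison, and of the 97 genes 61 were higher with RU486 and rose with DHT (4.39 for independent lists), 27 were lower and fell (1.84 for independent lists) and 0 went opposite ways. For Dex the numbers were 44 (8.74 for independent lists), 22 (3.97) and 5. Across 9731 genes, which are not independent replicates, RU486 minus CPA had r = 0.396 and rho = 0.195 with the DHT change, and r = 0.206 with the Dex change.

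**Figure D4:**
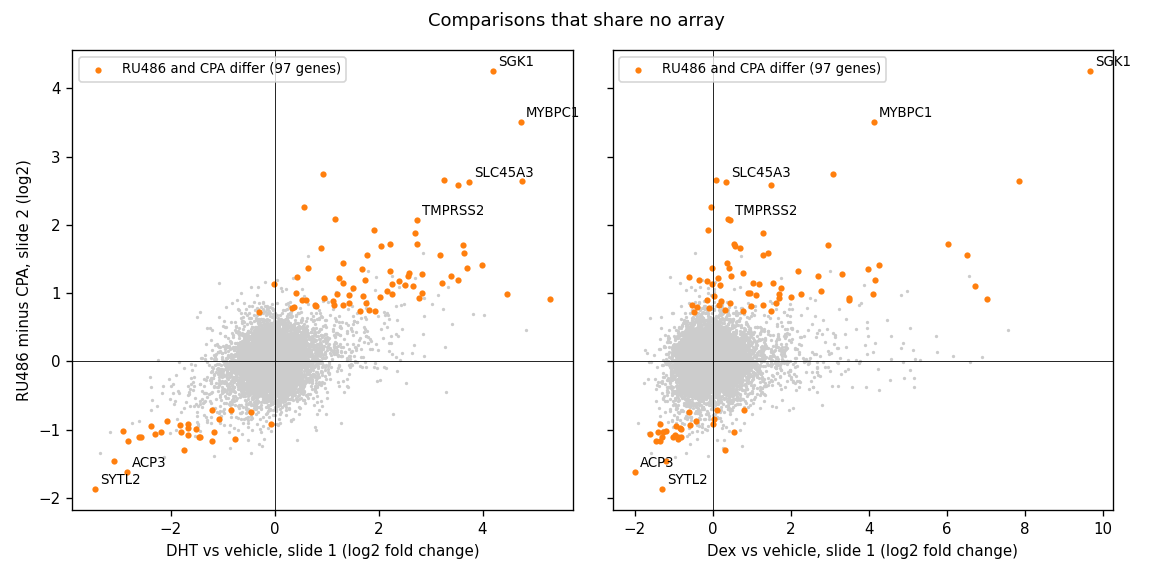
RU486 minus CPA log2 difference on slide 2 against the DHT change (left) and the Dex change (right) on slide 1, with the 97 genes that differed between CPA and RU486 in orange. Of the orange genes 61 lie up and 27 down in both for DHT, and 44 and 22 for Dex.

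The remaining lists gave few passing tests. Glycolysis genes ranged from adjusted p = 0.121 with DHT (4 up of 19) to 0.996 with Dex, although the glucose transporter SLC2A3 rose with DHT (1.55, SE 0.18), Dex (0.85, SE 0.18) and DHT+Dex (1.65, SE 0.18). Immediate-early genes ranged from 0.101 for DHT+Dex vs DHT to 0.943 for DHT, with FOS at least 10.1-fold higher with Dex and at least 23.8-fold with DHT+Dex, and MYC at -0.87 (SE 0.18) and -1.89 (SE 0.18). Interferon-stimulated genes ranged from 0.0935 to 0.981, and with DHT+Dex 1 rose and 4 fell of 10, IFIH1 being at least 4.90-fold lower. That list passed, shifted down, for DHT against vehicle without Vehicle 1 (camera adjusted p = 0.0409). For DHT+Dex against Dex it passed, shifted down, with median centring (camera adjusted p = 0.0434). The list of steroid receptors, pioneer factors and cofactors ranged from 0.280 to 0.906. In it the transcription factor gene GATA2 fell with DHT (-1.06, SE 0.13), Dex (-0.66, SE 0.13) and DHT+Dex (-2.02, SE 0.13), and the coactivator NCOA1 rose with Dex (0.67, SE 0.13) and DHT+Dex (1.09, SE 0.13). Heat shock genes ranged from 0.263 to 0.982, with BAG3 up by 0.74 (SE 0.12) with Dex. Of 4 measured NF-kappaB genes (adjusted p from 0.288 to 0.996) TNFAIP3, an inhibitor of that pathway, was at least 2.68-fold higher with Dex and at least 4.08-fold with DHT+Dex, while NFKB1 fell (-0.48, SE 0.12, and -0.62, SE 0.12). In this list the mean (0.38 and 0.40) and the median (-0.22 and -0.33) differed in sign in these comparisons, as they did for glycolysis genes with DHT (mean 0.25, median 0.00) and luminal markers with Dex (0.33 and -0.09). With median centring the calls of GATA2 with DHT and Dex (adjusted p = 0.0582 and 0.191), NCOA1 with Dex (0.0599) and NFKB1 with Dex and DHT+Dex (0.411 and 0.231) ended.

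Markers of other cell types were mostly undetected. Of the basal markers 0 were tested, and of the leukocyte markers only CD68, a lysosomal protein that epithelial cells can also express, which rose by 3.05 (SE 0.21) with Dex and 3.29 (SE 0.21) with DHT+Dex. Of the neuroendocrine markers ENO2 and TUBB3 were tested, and ENO2 fell with DHT (-1.21, SE 0.14), Dex (-0.74, SE 0.14, and adjusted p = 0.141 with median centring) and DHT+Dex (-2.02, SE 0.14). Of 3 fibroblast markers DCN was at least 1.07-fold higher with Dex, and against vehicle the list did not pass (adjusted p from 0.174 to 0.871). Luminal markers had adjusted p = 0.0426 with DHT, as above, and from 0.0866 to 0.862 in the other comparisons, with KRT8 up by 2.74 (SE 0.12) with Dex and 3.43 (SE 0.12) with DHT+Dex. With median centring the luminal list passed for CPA against RU486, lower with CPA (adjusted p = 0.0185).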

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

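The tests of exchanged CPA and RU486 labels, of the slides as the source of the androgen-type response on the RU486 arrays, of the interaction size without the quantile step and of added levels over all genes that rose with both hormones and on arrays left out of their choice were chosen only after the result was seen, as was the spread over arrays named for the brightest probes.

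The response to DHT differed with and without Dex at 292 genes, 88 with a positive and 204 with a negative interaction, by limma's test of the difference itself (n = 3 per group). Fitted on the 12 arrays of slide 1 alone, the term passed at 196 genes. Of 100 drawn splits of these arrays into 4 groups of 3, 2 gave as many, the real one included. The other such split gave 2956 genes and set all vehicle and DHT arrays against all Dex and DHT+Dex arrays, so it points to a structure of the samples, the Dex difference itself. The next highest split gave 14 genes and 94 splits gave 0. Drawn groups mix treatments, so the DHT and Dex differences widen the spread within them and can lower their counts. The share of splits therefore does not decide chance for the interaction. For the comparisons of 3 arrays with 3, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. In fits on the 6 arrays compared, the real split gave 856 genes for DHT against vehicle, 2097 for Dex against vehicle, 4051 for DHT+Dex against vehicle, 1589 for DHT against Dex, 2838 for DHT+Dex against DHT and 745 for DHT+Dex against Dex, and the highest other split gave 0 in each.

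Signals also appeared among 2019 detected probes with no listed gene, which no comparison by gene used. With DHT 186 of these probes differed from vehicle, 110 up and 76 down (limma, Benjamini-Hochberg). With Dex 368 differed, 187 up and 181 down. With DHT+Dex 713 differed, 292 up and 421 down.

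The CPA and the RU486 arrays differed from vehicle alike at 128 genes, all but 12 of them upward, among them TXNL1, FZD6, SNX10, DBR1 and OSBPL8, and only 1 of the 128 differed between CPA and RU486. Unchanged groups simulated with shared vehicle arrays shared at most 1 gene. Their noise was independent between genes, so almost no calls arise there. Noise common to many genes on the vehicle arrays was not simulated, so sharing these arrays stays open as a source. A probe-level difference between the slides stays open: at the 26 genes with several probes the other probes moved by a median of 0.434 times the probe used (95% interval 0.175 to 0.903), against 0.790 for genes changed by DHT, and 23.1% of them against 7.06% went the opposite way. A response that DHT or Dex also gives stays open as well, since 26.6% of the 128 genes (19.1 to 35.1%) had the sign of a DHT or Dex call. The share of like calls over all genes was not computed, and the shared vehicle arrays can raise the 26.6%. Of all 9731 genes, 12.9% passed with DHT and 26.8% with Dex, in either direction. Both compounds lie on slide 2 and vehicle on slide 1, so slide and compound cannot be told apart for these genes, which may follow the slide and not either compound.

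Of 316 genes that rose with DHT and with Dex, 296 rose under DHT+Dex by less than the sum of the single log2 rises, with 108 negative and 0 positive interaction calls and FKBP5, SOCS2 and SNAI2 among the largest. Signals near the upper end of the array scale are argued against for all but ODC1, PGC, S100P, SGK1 and TIPARP, the 5 genes (4.63%, the same on each DHT+Dex array) within 1 log2 unit of the brightest probe, where the 108 genes had a median level of 10.51 against 15.58, although the interval over genes chosen beforehand, 1.52 to 10.5%, crossed its bound of 10%. Without the quantile step the 108 terms had a median of -1.51 (median SE 0.381) against -1.40 (median SE 0.224), and all stayed negative. That setting also shifted the interaction of all genes by a median of -0.14, so a larger term was not shown. A term of like size without the step argues against quantile normalization as the source of its size. Only 54.6% (44.8 to 64.2%) passed, short of the bound of 90% set beforehand. Why the other calls ended was not tested, so for the calls this explanation stays open. Levels that add up on the linear scale may account for the median of the pattern, but not for each gene. Genes were chosen without 1 vehicle, 1 DHT and 1 Dex array and measured on those left out. The median ratio of the DHT+Dex level to DHT plus Dex minus vehicle was then 0.973 (0.921 to 1.05 over 27 such choices, which share arrays). The median interaction was -0.71 (-0.85 to -0.41). Single genes spread widely, with quartiles of the ratio at 0.790 and 1.09 over the 316 genes. Of these, 20 were lower with DHT+Dex than with DHT alone and 180 were higher. Added levels do not give such a fall at genes that Dex raised, which argues against them at these 20 genes. Over the 108 genes the ratio was 0.774 (0.735 to 0.830), wholly below the bound set beforehand, which by that rule counted against added levels. Over all 316 genes it was 0.918 (0.8995 to 0.961). Both sets were chosen by levels that enter these ratios, so neither ratio decides.

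The intervals in this section run over genes, which are not independent replicates, and do not measure the spread between arrays. At the 619 genes that rose with DHT, RU486 minus CPA (2 arrays each) had a median of 0.184 (0.157 to 0.216). It was positive at 74.3%, while the highest of 1000 random lists matched on mean level had a median of 0.0400. Both compounds lie on slide 2, so the median of 0.184 argues against a difference between the slides as the source of the androgen-type response. An exchange of the CPA and RU486 labels stays open: at the 871 genes that rose with Dex and were not called with DHT, RU486 minus CPA had a median of 0.00518 (-0.00778 to 0.0212), which a compound without activity at these genes gives under either labelling. The labels also conflict on the RU486 dose, whose effect was not tested. No biological explanation of the pattern was tested, and neither compound was combined with DHT or Dex here.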

How the results depend on the processing

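Leaving out single arrays and median centring for the gene lists, leaving out genes shared by CPA and RU486, and the alternatives for 18 genes named from lists that did not pass or below the 4 smallest p of a list, were tests chosen only after the result was seen. Of 400 values of 156 named genes none reversed in the 9 alternatives run for them or without single arrays. Median centring kept 335 of them on their side of the threshold, leaving out single arrays 347, and the other 8 alternatives at least 385. All probes tested separately, the mean of the probes, only the groups compared and the other thresholds were run for the counts alone. Of 170 pairs of a list and a comparison 65 passed, against 51 with an estimated correlation (14 lost), 64 with the replicate block, 64 with no background correction (2 lost, 1 gained), 58 with median centring (9 lost, 2 gained) and 109 with fry (44 gained, as fry tests whether a list moves and not whether it moves more than other genes), and no call turned. The authors' processed intensities, the filter on all arrays of a group, the mean of a gene's probes and a change of at least 1.5-fold gave counts within 1.5 times the main ones.

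Median centring gave 722 genes for DHT, 1031 for Dex and 2866 for DHT+Dex against vehicle, 1094 for DHT against Dex, 2017 for DHT+Dex against DHT, 383 for DHT+Dex against Dex, 108 for the interaction and 32 for CPA against RU486. It gave 283 calls shared by DHT and Dex, a correlation of 0.448, 18 shared calls of CPA with Dex, 125 of RU486 with DHT and 77 of RU486 with Dex. The median CPA changes over genes that rose and fell with DHT and with Dex went from 0.01, -0.11, -0.01 and -0.08 to 0.22, 0.09, 0.18 and 0.17. The median RU486 changes went from 0.24, -0.30, 0.04 and -0.11 to 0.58, -0.25, 0.33 and 0.06. It shifted the median of all genes by 0.21 for DHT, 0.16 for DHT+Dex, 0.13 for DHT against Dex, -0.14 for the interaction, 0.23 for CPA and 0.31 for RU486, and the share of rises among calls rose from 49.1 to 71.6% for DHT and from 47.2 to 73.5% for Dex. The quantile step and the larger spread without it both differ between these settings, and the cause was not tested.

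An adjusted p under 0.01 passes fewer genes by construction: 769 for DHT, 1502 for Dex, 57 for CPA and 179 for RU486 against vehicle, 1192 for DHT against Dex, 2322 and 548 for DHT+Dex against DHT and Dex, 120 for the interaction and 41 for CPA against RU486. A fit on only the groups compared has fewer arrays behind the spread and gave 745 genes for DHT+Dex against Dex, 24 for CPA, 211 for RU486 and 58 for CPA against RU486. For the alternatives that follow the cause was not tested. No filter gave 194 genes for the interaction, 135 for CPA and 272 for RU486, and 13, 20 and 96 shared calls of CPA with DHT, CPA with Dex and RU486 with Dex. No background correction gave 519 for CPA and 672 for RU486, with 53 and 99 shared calls of CPA with DHT and Dex. Normalizing each slide alone gave 751 and 961 genes, and shifted the median of all genes by 0.22 in both. For CPA all probes gave 475, trend and robust options 472 and array weights 478, and array weights gave 878 for RU486 and 246 for CPA against RU486. Without the genes shared by both compounds 110 remained for CPA and 296 for RU486. The replicate block gave 365 genes for CPA, 69 shared calls of CPA with Dex, and 1337 for DHT, 2720 for Dex, 4699 for DHT+Dex and 278 for the interaction. Whether the numbers pair the arrays stays open. Residuals of arrays with 1 number had a median correlation of 0.03 over 18 pairs, from -0.03 to 0.23, with 3 over 0.1. Pairs of unlike number were not compared.

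Without each array in turn the counts ranged from 1005 to 1241 for DHT, 2010 to 2226 for Dex, 4183 to 4263 for DHT+Dex, 1611 to 1746 for DHT against Dex, 3044 to 3165 for DHT+Dex against DHT, 785 (without Dex 3) to 1008 for DHT+Dex against Dex and 201 to 263 for the interaction. They ranged from 1 to 191 for CPA, 97 to 363 for RU486 and 21 to 40 for CPA against RU486, and without 1 of the 2 arrays of these groups the remaining array was assumed to vary like the other groups. For CPA 1 gene passed without CPA 1, 15 without CPA 2, 128 without Vehicle 1 and 150 without Vehicle 2, and for RU486 118 without RU486 1 and 97 without RU486 2. For CPA against RU486 the counts were 40 and 21 without CPA 1 and CPA 2 and 26 and 25 without RU486 1 and RU486 2. Shared calls of DHT and Dex ranged from 547 to 692 and their correlation from 0.449 to 0.499, shared calls of CPA with DHT from 0 to 28 and with Dex from 0 to 47, those of RU486 with DHT from 62 to 186 and with Dex from 48 to 137, and list calls from 59 to 67. For CPA with DHT they were 0, 3, 11 and 19 without CPA 1, CPA 2, Vehicle 1 and DHT 1, and with Dex 0, 4 and 24 without CPA 1, CPA 2 and Vehicle 1. For RU486 they were 76 and 62 with DHT and 63 and 48 with Dex without RU486 1 and RU486 2. Signal over background limits what can be measured: from 23.4 to 26.9% of probes were detected on an array, and a gene undetected in 1 group has only a bound.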

Other observations

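The genes named here and their tests under median centring were chosen only after the result was seen.

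A small group of genes moved in opposite directions with the 2 hormones, and DHT+Dex mostly followed Dex. Of 45 genes that fell with DHT and rose with Dex, 44 were higher with DHT+Dex than with DHT alone and 36 were higher than with vehicle. KCNG1, a potassium channel gene, stood at -0.66 with DHT, 3.93 with Dex and 4.38 with DHT+Dex (SE 0.20, n = 3 per group, limma). CA12, a carbonic anhydrase gene, stood at -0.84, 2.40 and 2.54 (SE 0.22), and GPER1, a membrane receptor gene, at -1.14, 2.05 and 2.27 (SE 0.24), while EDN2, an endothelin gene, stood at 0.97 with Dex and 1.40 with DHT+Dex (SE 0.20). IGFBP3 stood at 0.67 and 0.62 (SE 0.18) and HSD11B2, whose enzyme inactivates cortisol, at 1.27 and 0.28 (SE 0.30), the last with adjusted p = 0.471. These 3 genes were detected on 1 of 3 DHT arrays and were at least 2.64-fold, 3.96-fold and 1.80-fold lower with DHT. All 30 genes that rose with DHT and fell with Dex were lower with DHT+Dex than with DHT alone, and 16 were lower than with vehicle. Among them were UGT2B28 at 3.30, -0.67 and 1.63 (SE 0.15), SLC2A12 at 1.95, -1.09 and 0.17 (SE 0.37, detected on 2 of 3 Dex arrays), ADAMTS1, a secreted protease gene, at 1.52, -0.72 and -0.65 (SE 0.21), and PAQR4 at 1.31, -1.12 and -0.98 (SE 0.13). With median centring all 75 genes kept both signs but only 8 kept both calls. GPER1, EDN2 and PAQR4 were among the 8. With DHT, KCNG1, CA12 and HSD11B2 missed the threshold (adjusted p = 0.337, 0.183 and 0.113), with KCNG1 at -0.49 and CA12 at -0.62. With Dex, IGFBP3, UGT2B28, SLC2A12 and ADAMTS1 missed it (adjusted p = 0.0625, 0.190, 0.0722 and 0.164), with IGFBP3 at 0.75 and ADAMTS1 at -0.63. The DHT call of KCNG1 also ended with no background correction (adjusted p = 0.0552).

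Many genes passed only when both hormones were given. Of the 4614 genes that passed with DHT+Dex, 1906 passed with neither hormone alone, 707 up and 1199 down, with a median size of 0.63 on the log2 scale. Both single changes had the sign of the DHT+Dex change at 1389 of these. The interaction term passed at 23 of the 1906 genes, so for the rest a response beyond the sum of the single changes was not shown. ELF5, an epithelial transcription factor gene, stood at -0.09 with DHT and -0.48 with Dex (SE 0.22, n = 3 per group) and was at least 2.83-fold lower with DHT+Dex, where 1 of 3 arrays detected it, with an interaction of -1.11 (adjusted p = 0.0747). JPH4 was undetected with vehicle, DHT and Dex and at least 1.84-fold higher than vehicle with DHT+Dex. With median centring all 1906 kept their sign and 764 passed.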
